A study of Mus musculus with 8 samples.

How the data were processed

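The series holds 8 Affymetrix mouse expression arrays of total RNA from acute myeloid leukaemia (AML) cell lines grown in serum-containing medium with the cytokine IL-3. The labels put 4 arrays in a group called Trib1 hi (cells expressing Hoxa9 and Trib1) and 4 in a group called Trib1 null (cells expressing Hoxa9 without Trib1), each numbered 1 to 4. Groups and replicate numbers were taken from the sample titles. The labels do not say that the arrays of a group came from separate cultures or animals, so p-values measure the spread between these samples, which may be technical.

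The authors deposited 1 table with a linear intensity for each of 45141 probe sets on each array. Per the submitters' processing notes the values come from MAS5, Affymetrix's statistical algorithm, which summarises the probes of a probe set and scales each array; its version and parameters are not given in the sources used here. The deposited intensities had a mean trimmed by 2% at both ends of 500.1 to 500.2 on every array, a lowest value of 1, and 374 to 1592 probe sets at that value. No detection calls were used here. The number of arrays, 4 per group, limits the precision.

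Gene symbols came from the platform annotation. Of the 45141 probe sets, 104 were Affymetrix controls, 29449 were listed in the annotation, 28898 had exactly 1 symbol and 551 had several. The other 15588 had no listed gene. Entrez identifiers of 28689 of the single-gene probe sets matched the gene table of the mouse assembly GRCm38.p6 and 209 did not; 0 symbols were updated. That table was used only for names, chromosomes and gene order, since the labels name no genome build. Each of the 17097 genes was represented by its probe set with the highest mean over all 8 arrays.

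The deposited values were tested as log2(intensity + 2.71), where 2.71 is the 25th percentile of all deposited values. A fold change on this scale understates the change of dim genes. Genes with a mean log2 value over 3.01, the 40th percentile of all probe sets, were kept, which left 12259. No further scaling was applied. limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend) compared the 4 arrays labelled Trib1 hi with the 4 labelled Trib1 null, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Every adjusted p of a gene comes from this model unless another test is named.

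The arrays differed at low intensity in a way that did not follow the groups alone, so levels near the bottom of the scale could not be compared. Folds were therefore computed after signals below 500 had been set to 500, a limit chosen after seeing the data. Where 1 group lay below 500 on some or all of its arrays and the other above it on each array, the fold is a lower bound and is written "at least". It bounds the ratio of deposited signals. An added control, dap, differed by -0.84 on the log2 scale at group means of 610 and 1073. Decreases written "at least" with a fold no larger than that cannot be told apart from such a difference in controls. No fold is given where both groups lay below 500 on some or all arrays, and measured means stand in its place. Means are of the deposited intensities, with SD and n = 4 arrays per group, and the group labelled Trib1 hi comes first unless stated.

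Before the data were examined, 30 gene lists, the test, the filter, the rule for named genes and a set of processing alternatives were fixed. The lists cover Trib1 and its partners, Hox genes and cofactors, genes singled out by the study, Hoxa9-bound genes from other work, stem and progenitor cells, primary granules, secondary granules and neutrophils, monocytes and macrophages, mast cells and basophils, eosinophils, erythroid and megakaryocytic cells, lymphoid cells, dendritic cells with MHC class II, fibroblasts with endothelial cells, C/EBP targets, MEK and ERK response, IL-3 and STAT5 response, the cell cycle, MYC with ribosome biogenesis, interferon-stimulated genes, NF-kB, cholesterol synthesis, amino acid with unfolded protein stress, hypoxia with glycolysis, p53 targets, apoptosis, adhesion and homing, PI3K with small G proteins, sex-linked genes and widely expressed control genes. Lists with at least 5 tested members were tested with limma's camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. camera asks whether a list moved relative to the other genes. Each list was tested again with an estimated correlation and with fry, which asks whether the members moved on balance in 1 direction without comparing them with other genes.

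The text names, by the fixed rule, the 10 genes with the largest increase and the 10 with the largest decrease in fitted log2 value among those past the threshold without overlap between the groups (symbols of RIKEN, Gm or LOC style skipped), then Trib1, Hoxa9, Meis1, Cebpa, Erg, Spns2, Rgl1 and Pik3cd whatever their result, and up to 4 members per list with the largest change among those past the threshold, or up to 2 as values only where none passed. Non-overlap of 4 against 4 values arises by chance in 2.86% of genes. A gene outside this rule was chosen after its values were seen, and its sentence says so.

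The alternatives fixed beforehand were other pseudocounts, other filters, quantile normalization, equal medians over the tested genes, other rules for several probe sets of a gene, the replicate number as a block, other variance priors, a per-gene test without a shared variance, and leaving out each array in turn. Alternatives chosen after seeing the data were floors of 500 and 1000, quantile normalization with a floor of 500, leaving out both arrays with raised low intensities, and leaving out chromosomes 8, 17 and X. Chromosome medians over genes with a mean signal over 1000 were compared with those of 10000 random gene draws of the same size. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

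The gene test was checked on simulated data for the same 12259 genes and this comparison, with 200 genes changed. It recovered 51 of 100 genes changed by 0.5 on the log2 scale and 91 of 100 changed by 1, with 12 false calls. The changed genes were drawn only from those with a mean log2 value above that of a signal of 500. Recovery among dimmer genes was thus not checked, and 5906 of the 12259 had a mean signal under 250. A simulated list of 25 genes from the same brighter set, shifted by 0.5, was called, and 0 of the unshifted simulated lists were. The simulated noise was independent between genes. Deviations that many genes of an array share were thus absent, and the check does not cover them. Of the deposited probe sets, 16139 without a single gene name were left out of the tests.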

Results

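Gene expression was measured on 8 arrays, 4 labelled Trib1 hi and 4 labelled Trib1 null. Both groups are mouse AML cell lines that express Hoxa9, a homeobox transcription factor that drives myeloid leukaemia, and the leukaemia cells arose in mice lacking both copies of Trib1. Trib1 is a pseudokinase that, with the ubiquitin ligase COP1, brings about degradation of the transcription factor C/EBP alpha and binds the kinase MEK1. The comparison asks how gene expression differs between cells driven by Hoxa9 that are labelled as with and without Trib1. The groups may also differ as cell lines, since Xist and genes of chromosome 17 differed between them (below). Such a difference cannot be told apart from an effect of Trib1 with these arrays.

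Intensities lay closest near the 90th percentile and spread below and above it. The 90th percentile lay between 1808 and 1985 on all 8 arrays and the 95th between 3733 and 4967, lowest on Trib1 hi 3 in both cases, whereas the 75th percentile ran from 15.5 to 422 and the median from 3.71 to 68.3. The background control probe set GC25 read 11.4 to 379. Its highest readings were 379 on Trib1 hi 3 and 335 on Trib1 null 1, and the other 3 arrays labelled Trib1 hi read 15.1 or less. The added control transcript dap read lower in the arrays labelled Trib1 hi without overlap, by -0.50, -0.84 and -0.54 on the log2 scale at group means from 610 to 2963, so a difference in controls reached signals above 500, whereas the brighter controls bioD and cre differed by 0.06 or less. Between 17.7% and 23.2% of probe sets exceeded 500. The 3'/5' ratios of Actb, 1.07 to 1.15, and Gapdh, 0.852 to 0.894, overlapped between the groups. Spearman correlations over all probe sets except controls were 0.973 to 0.979 within the group labelled Trib1 hi, 0.957 to 0.967 within the group labelled Trib1 null and 0.943 to 0.952 between groups.

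**Figure D1:**
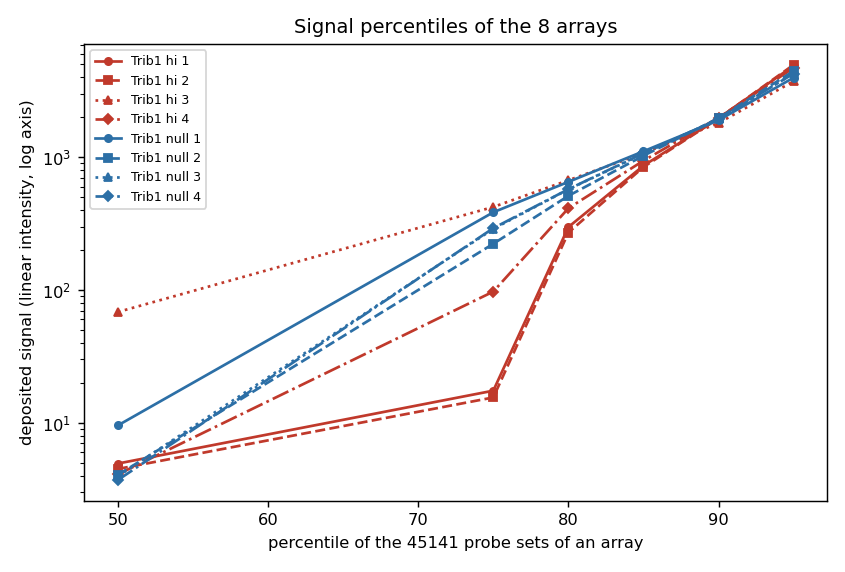
Deposited signal (linear intensity, log axis) at the 50th, 75th, 80th, 85th, 90th and 95th percentile of the 45141 probe sets of each array (red, Trib1 hi; blue, Trib1 null; 1 line per array). The arrays spread from 15.5 to 422 at the 75th percentile come together between 1808 and 1985 at the 90th, and spread again from 3733 to 4967 at the 95th.

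The targeted gene read against its label, but in the range where arrays differ. The brighter of both Trib1 probe sets read 7.13, 7.13, 122 and 5.92 on the arrays labelled Trib1 hi and 304, 223, 212 and 206 on those labelled Trib1 null. The other had means of 9.05 ± 12.6 and 6.98 ± 6.54. The fitted difference of the brighter probe set was -3.72 on the log2 scale (adjusted p = 0.0497), and the call ended when any array except Trib1 hi 3 was left out (adjusted p = 0.0959 to 0.165). After quantile normalization the difference was -2.24 (adjusted p = 1.35e-07), against -0.15 for the dim control bioB, and the adjusted p ranged over alternatives from 1.35e-07 to 0.240. All 8 values lie below 500, in the range where arrays differ. Those of the group labelled Trib1 null (206 to 304) lie at the level of the GC25 background control there (149 to 335), though above the array medians (3.71 to 9.56). The Trib1 values therefore do not test the label. Hoxa9, which the labels give to both groups, also fell, from 1024 ± 43.5 in the group labelled Trib1 null to 107 ± 189 in the group labelled Trib1 hi, at least 2.05-fold lower (adjusted p = 5.01e-06), a call that ended without a shared variance (0.121) and with a floor of 1000 (0.179, range over alternatives 1.68e-12 to 0.179). Where these probe sets lie relative to the deleted part of Trib1 or to the introduced Trib1 and Hoxa9 sequences is not given in the sources used here, and a probe outside those parts checks nothing. Because Trib1 read against the labels, groups are called the arrays labelled Trib1 hi and the arrays labelled Trib1 null throughout, and each direction is that of the labels.

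Of 12259 genes, 1362 were higher and 2405 lower in the arrays labelled Trib1 hi, 275 and 1202 of them by at least 2-fold on the fitted scale. Quantile normalization gave 3336 higher and 3345 lower, with 882 and 888 at 2-fold. With a floor of 500, the limit used for folds, 192 genes were higher and 336 lower by at least 2-fold. Equal medians gave 5440 higher and 250 lower; that scaling moved the median log2 difference of all tested genes from 0.04 to 2.02, against 0.01 under quantile normalization. Of the 1362 genes called higher, 1359 were called higher after quantile normalization and 1263 with a floor of 500; of the 2405 called lower, 2174 and 1758. No call (0) was opposite after quantile normalization. Brightness shaped the split: 756 genes were higher and 590 lower over a mean signal of 2000, against 20 and 230 under 250. Without Trib1 hi 3, 2092 genes were higher and 3762 lower, 2323 of the latter by at least 2-fold.

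Among the largest increases in the arrays labelled Trib1 hi, Cth, which makes cysteine from cystathionine, read 4499 ± 539 against 1.52 ± 0.161 (at least 8.95-fold higher, adjusted p = 3.25e-12). Mpo, the myeloperoxidase of primary granules, read 5201 ± 755 against 2.92 ± 0.791 (at least 10.3-fold higher, adjusted p = 4.36e-14). Cd34, a surface protein of blood progenitors, rose at least 6.81-fold, and Nkg7, a granule membrane protein, at least 5.32-fold. Ptgds, a prostaglandin D synthase, rose at least 20.1-fold to 10143 ± 1592. Bcat1, which transfers amino groups of branched-chain amino acids, rose at least 2.69-fold, Stc2, a secreted glycoprotein, at least 3.93-fold, and F7, coagulation factor VII, at least 2.50-fold. Rgs5, a regulator of G protein signalling, rose at least 6.30-fold and Plxdc2 at least 3.27-fold. Adjusted p was 2.17e-06 or smaller for all 10.

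Among the largest decreases, Csn2, the milk protein beta-casein, fell from 24718 ± 2173 to 67.3 ± 116 (at least 49.3-fold lower, adjusted p = 5.83e-17). Xist, the RNA that silences an X chromosome, fell from 8907 ± 684 to 29.7 ± 48.0 (at least 17.8-fold lower). Lrg1, a secreted neutrophil glycoprotein, was at least 9.79-fold lower, Ets1, a transcription factor, at least 8.83-fold, and Erdr1 at least 8.84-fold. Chil3, a chitinase-like lectin of myeloid cells, was at least 3.17-fold lower, Alcam, an adhesion molecule, at least 3.15-fold, and Frmd4b at least 2.88-fold. Cd177, a neutrophil surface protein, was at least 2.38-fold lower and Pawr, a regulator of apoptosis, at least 1.37-fold. Adjusted p was 0.000232 or smaller for all 10. The plot of signals of named genes shows how far the groups lay apart.

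**Figure D2:**
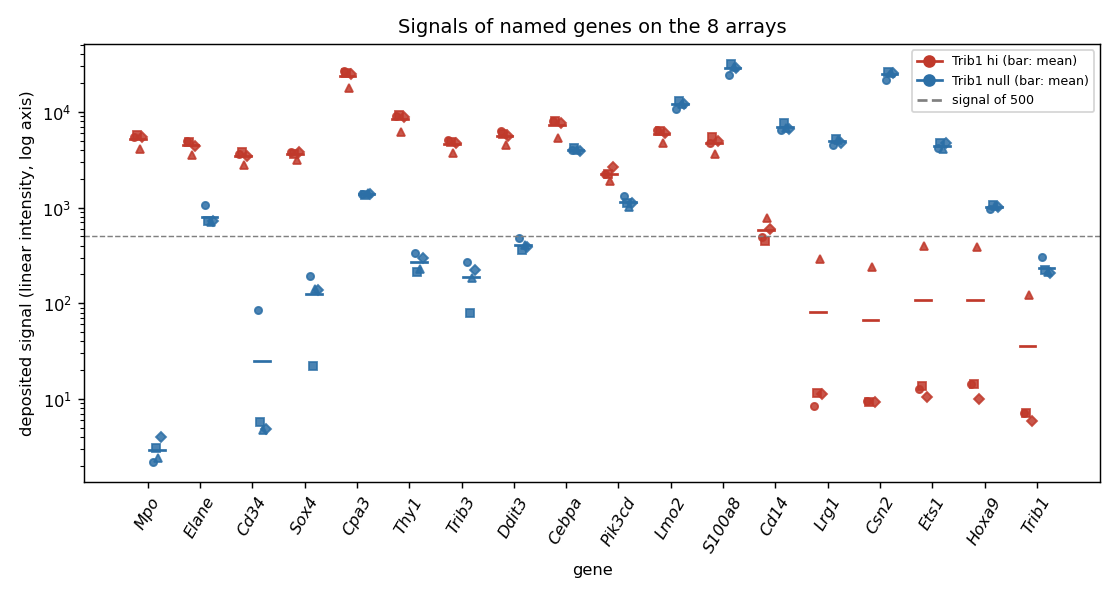
Deposited signal (linear intensity, log axis) of 18 genes on the 4 arrays labelled Trib1 hi (red) and the 4 labelled Trib1 null (blue); symbols mark replicates, bars the group means and the dashed line a signal of 500. Below that line Trib1 hi 3 (red triangles) lies above the other arrays of its group, as for Trib1 (122 against 7.13 or less) and Hoxa9 (391 against 14.3 or less).

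By camera, 6 gene lists shifted up and 7 down, against 1 up and 2 down with an estimated correlation. Counting the larger of both directions, since a split and its mirror are the same, 24 of the 35 possible splits of the 8 arrays into 4 and 4 gave 7 lists or more in a direction. Genes of ribosome assembly rose together in the arrays labelled Trib1 hi. Of 25 tested members of the MYC and ribosome biogenesis list, 17 rose and 0 fell (18 and 0 adjusted over the list alone). Nop56 and Nop58, proteins of the box C/D ribonucleoprotein that modifies ribosomal RNA, rose 2.87-fold (7352 ± 988 against 2550.3 ± 256) and 2.65-fold (11602 ± 2232 against 4321 ± 367). Nolc1, a nucleolar chaperone, rose 2.69-fold and Ppan, a ribosome assembly factor, at least 2.63-fold. The list shifted up by camera (adjusted p = 8.57e-14, adjusted p = 0.0309 with an estimated correlation, range over alternatives 9.36e-16 to 0.0339).

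The list of amino acid and unfolded protein stress genes also shifted up. Of 29 tested members, 18 rose and 4 fell (18 and 4 adjusted over the list alone). Ddit3, the stress transcription factor CHOP, read 5572 ± 791 against 409 ± 51.1 (at least 11.1-fold higher, adjusted p = 2.38e-22). Trib3, a relative of Trib1 induced by stress, rose at least 9.10-fold and Atf5 at least 4.61-fold. Atf4, the transcription factor that drives this response, rose 2.95-fold (19577 ± 3657 against 6547 ± 397), and the serine synthesis enzymes Phgdh and Psat1 4.58-fold and 3.28-fold; these 3 were chosen after their values were seen. The 4 that fell, named after their values were seen, assist protein folding in the endoplasmic reticulum or are induced by misfolded protein there: Creld2 (1.62-fold), Sdf2l1 (1.48-fold), Dnajb9 (1.28-fold) and Pdia4 (1.22-fold). The Pdia4 call (adjusted p = 0.0191) ended without Trib1 hi 1 (0.127) or Trib1 null 2 (0.0598, range over alternatives 0.00289 to 0.152). The list's shift (adjusted p = 5.80e-14) missed the threshold with an estimated correlation (adjusted p = 0.0518 with an estimated correlation, range over alternatives 2.18e-33 to 0.0518).

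Mature neutrophil genes fell. Of 31 tested secondary granule and neutrophil genes, 16 fell and 1 rose (16 and 1 adjusted over the list alone; camera adjusted p = 7.99e-07, adjusted p = 0.0441 with an estimated correlation, range over alternatives 1.35e-10 to 0.0441). Besides Lrg1, Chil3 and Cd177, Cybb, a subunit of the NADPH oxidase, fell at least 2.32-fold. S100a8 and S100a9, which form calprotectin, were chosen after their values were seen: they fell from 28450.2 ± 3038 to 4684 ± 757 (6.11-fold) and from 32605 ± 3094 to 8541 ± 1428 (3.85-fold).

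C/EBP target genes, many of them shared with the neutrophil list, divided. Of 30 tested, 14 fell and 5 rose (14 and 5 adjusted over the list alone), and camera placed the list down (adjusted p = 0.00792, adjusted p = 0.0623 with an estimated correlation, adjusted p = 0.218 without Trib1 hi 3, range over alternatives 9.00e-06 to 0.218). Id2, a dominant-negative helix-loop-helix protein, fell at least 2.62-fold and Hlx read 53.9 ± 95.9 against 414 ± 98.3 (adjusted p = 0.00574, 0.659 with a floor of 500, range over alternatives 3.05e-08 to 0.659). Cebpa itself rose 1.80-fold, from 4002 ± 109 to 7291 ± 1285 (adjusted p = 1.58e-07, 0.0586 without a shared variance, range over alternatives 1.80e-12 to 0.0586), higher on 4 of 4 arrays. Cebpb, its relative, rose 1.35-fold (13550.3 ± 2087 against 9918 ± 409, adjusted p = 0.00634, 0.431 with the mean of its probe sets, range over alternatives 1.87e-07 to 0.431). With Trib3 these make the 3 higher members of 6 tested on the list of Trib1 and its partners, where 2 fell (3 and 2 adjusted over the list alone), Trib1 itself and Map2k1, which encodes MEK1 and was named after its values were seen (1.31-fold lower). That list passed narrowly (adjusted p = 0.0483, adjusted p = 0.222 with an estimated correlation), and its call ended without any of the 4 arrays labelled Trib1 hi (adjusted p = 0.0567 to 0.0837, range over alternatives 2.10e-05 to 0.889).

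Primary granule genes moved apart. Of 16 tested, 5 rose and 2 fell (5 and 2 adjusted over the list alone). Elane, neutrophil elastase, rose 5.58-fold (4452 ± 653 against 802 ± 170.2, adjusted p = 3.94e-17), along with Mpo and Nkg7, and Dmkn read 676 ± 152 against 9.85 ± 12.1 (adjusted p = 0.000211). The median log2 difference of the list was -0.04 while its mean was 1.59, and camera, whose direction was up, missed the threshold (adjusted p = 0.0516). The list passed without Trib1 hi 3 (adjusted p = 0.00907) and without each array labelled Trib1 null (0.0193, 0.00157, 0.00019 and 0.000229 for replicates 1 to 4), and its direction was down after quantile normalization (adjusted p = 0.950, range over alternatives 7.69e-05 to 0.995).

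Markers of other myeloid lineages went both ways. Cpa3, the carboxypeptidase of mast cells and basophils, rose 16.8-fold (23607 ± 4093 against 1385 ± 22.4, adjusted p = 1.04e-23), and the transcription factor Gata2 2.41-fold, whereas the chemokine Ccl3 fell 2.52-fold. Of 16 tested mast cell and basophil genes, 3 rose and 3 fell (4 and 3 adjusted over the list alone), and the list did not shift (adjusted p = 0.293). Of 6 tested eosinophil genes, 3 rose and 0 fell (3 and 0 adjusted over the list alone): Siglecf, an eosinophil surface lectin (at least 8.04-fold), the lipoxygenase Alox5 (at least 2.53-fold) and Adgre1, a surface receptor also carried by macrophages (1.44-fold). That list shifted up (adjusted p = 0.000649, adjusted p = 0.0518 with an estimated correlation, range over alternatives 3.17e-07 to 0.0518). Of 26 monocyte and macrophage genes, 10 fell and 4 rose (10 and 4 adjusted over the list alone). Cd14, the co-receptor for lipopolysaccharide, fell from 6931 ± 528 to 578 ± 145 (at least 11.8-fold, adjusted p = 1.87e-21), Gpnmb at least 3.79-fold, Mpeg1 at least 1.87-fold and Clec7a at least 1.30-fold. Lgals3, chosen after its values were seen, rose 5.94-fold. The monocyte list did not shift (adjusted p = 0.145) but did so downwards after quantile normalization (adjusted p = 0.0234, range over alternatives 0.000511 to 0.373).

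Stem and progenitor cell genes showed 7 increases and 2 decreases among 31 (7 and 2 adjusted over the list alone). Sox4, a transcription factor of immature cells, rose at least 7.16-fold (3591 ± 310.3 against 124 ± 72.4), Msi2, an RNA-binding protein of stem cells, at least 1.41-fold, and Cd34 as above. Kit, the stem cell factor receptor, read 379.9 ± 208 against 77.3 ± 41.2 (adjusted p = 0.0159), a call that ended without Trib1 hi 2 (0.0645) or Trib1 hi 4 (0.0920, range over alternatives 1.46e-07 to 0.690). Lmo2, chosen after its values were seen, fell 2.06-fold. The list shifted up (adjusted p = 0.0172, adjusted p = 0.222 with an estimated correlation, adjusted p = 0.110 after quantile normalization, range over alternatives 0.000521 to 0.263), with a median log2 difference of 0.28 and a mean of 0.85. Of 18 genes bound by Hoxa9 in other work, 5 rose and 3 fell (5 and 3 adjusted over the list alone), among the latter the transcription factor Dach1 (3.00-fold). This list did not shift (adjusted p = 0.407) but passed upwards without Trib1 null 3 (adjusted p = 0.0368) or Trib1 null 4 (0.0347, range over alternatives 0.0205 to 0.845). Of 12 Hox genes and cofactors, 0 rose and 3 fell (0 and 3 adjusted over the list alone; list adjusted p = 0.407): Hoxa9 and the cofactors Pbx2 (at least 2.28-fold) and Pknox1 (1.48-fold), both on chromosome 17. The cofactor Meis1 was near the bottom of the scale, at 19.7 ± 31.5 against 5.31 ± 3.93 (adjusted p = 0.644).

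The 4 genes singled out by the study were measured without a list test. Pik3cd, a catalytic subunit of phosphoinositide 3-kinase, rose 1.99-fold (2263 ± 306 against 1138 ± 129.6, adjusted p = 1.36e-08), higher on 4 of 4 arrays, a call that ended with the mean of its probe sets (adjusted p = 0.495, range over alternatives 1.19e-15 to 0.495). Spns2, a transporter of sphingosine 1-phosphate, rose at least 1.67-fold (838 ± 63.6 against 325 ± 47.6, adjusted p = 3.90e-06). Erg, a transcription factor of blood stem cells, read 1671 ± 86.1 against 1449 ± 79.7 and missed the threshold (adjusted p = 0.137). Its difference passed after quantile normalization (adjusted p = 0.000964), with a floor of 500 (0.0248), and without Trib1 hi 3 (0.0213). The adjusted p of Erg over all alternatives ran from 0.000964 to 0.344. Its other probe set, below 500 on every array, had means in the opposite direction (93.7 ± 163 against 198 ± 75.2). Rgl1, an exchange factor of the Ras family, read 444 ± 179.9 against 259 ± 27.1 (adjusted p = 0.132; 1.25e-06 after quantile normalization, range over alternatives 1.25e-06 to 0.754). Adjusted over the list alone, 2 rose and 0 fell; these genes were taken from what is known of the study itself, so the list is not independent evidence of its direction.

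Phosphoinositide 3-kinase and small G protein genes as a group went the other way from Pik3cd. Of 20 tested, 11 fell and 1 rose (12 and 1 adjusted over the list alone). Rap1gap2, a GTPase activator, fell at least 2.86-fold, Rasgrp2, an exchange factor, at least 1.99-fold (adjusted p = 0.420 with the mean of its probe sets, range over alternatives 1.89e-15 to 0.891), Vav1, a haematopoietic exchange factor, at least 2.26-fold and Pik3cb, the beta catalytic subunit, at least 2.12-fold. The list shifted down (adjusted p = 0.00596, adjusted p = 0.222 with an estimated correlation, adjusted p = 0.0837 without Trib1 hi 3, range over alternatives 0.000902 to 0.442). MEK and ERK response genes fell in 9 of 27 cases and rose in 2 (10 and 3 adjusted over the list alone). Spry1, which restrains Ras signalling, fell at least 1.63-fold and the phosphatase Dusp2 at least 1.62-fold; Egr1 and Dusp6, chosen after their values were seen, fell at least 5.21-fold and 2.61-fold. Spry2 read 31.5 ± 51.1 against 518 ± 16.3 (adjusted p = 0.00102, 0.401 with a floor of 500, range over alternatives 1.45e-10 to 0.401), and Etv5 297 ± 212 against 24.8 ± 39.2 (adjusted p = 0.0373), a call that ended without Trib1 hi 1, 2 or 4 or Trib1 null 3 or 4 (adjusted p = 0.0592 to 0.168). This list passed narrowly (adjusted p = 0.0479, adjusted p = 0.540 with an estimated correlation, adjusted p = 0.0701 without Trib1 hi 3, range over alternatives 0.00671 to 0.540).

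Cholesterol synthesis genes fell as a group. Of 19 tested, 15 fell and 0 rose (16 and 0 adjusted over the list alone). The sterol reductases Tm7sf2 and Dhcr7 fell at least 2.77-fold and at least 2.05-fold, and Hsd17b7 fell at least 1.43-fold. Nsdhl, another enzyme of the pathway, chosen after its values were seen, fell 2.07-fold, from 3913 ± 248 to 1893 ± 93.9. Mvk, mevalonate kinase, read 160.2 ± 206 against 439 ± 34.5 (adjusted p = 0.00906), with overlapping groups, since Trib1 hi 3 read 458, and a call that ended with no filter (0.0616, range over alternatives 0.000915 to 0.533). The list shifted down (adjusted p = 1.94e-06, adjusted p = 0.0309 with an estimated correlation, range over alternatives 2.67e-09 to 0.0924).

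Interferon and inflammatory genes fell as well. Of 29 interferon-stimulated genes, 14 fell and 0 rose (16 and 0 adjusted over the list alone; camera adjusted p = 0.00214, adjusted p = 0.540 with an estimated correlation, range over alternatives 4.03e-05 to 0.540). Most were dim. Cmpk2 fell at least 1.19-fold (adjusted p = 0.280 after quantile normalization with a floor of 500, range over alternatives 1.29e-08 to 0.280), and Isg20, an exonuclease chosen after its values were seen, at least 3.02-fold. Rsad2 read 57.2 ± 101 against 375 ± 90.8, Dhx58 47.1 ± 77.9 against 360.0 ± 100.2 and Gbp2 49.8 ± 80.4 against 334 ± 73.8; their calls (adjusted p = 0.00983, 0.0110 and 0.0151) ended without Trib1 null 3 or 4, and those of Dhx58 and Gbp2 also without Trib1 null 1 (adjusted p = 0.0578 to 0.0954). Of 19 NF-kB and inflammatory genes, 9 fell and 2 rose (9 and 2 adjusted over the list alone; camera adjusted p = 0.0172, adjusted p = 0.540 with an estimated correlation, range over alternatives 0.00641 to 0.540). Nfkbie and Nfkbiz, of the I kappa B family, fell at least 2.49-fold (adjusted p = 0.145 where probe sets shared between transcripts were left out, range over alternatives 3.08e-15 to 0.145) and at least 1.24-fold (adjusted p = 0.376 with the mean of its probe sets, range over alternatives 1.30e-10 to 0.376). The chemokine Ccl4 read 124 ± 174 against 553 ± 63.7 (adjusted p = 0.00115, 0.145 with a floor of 500, range over alternatives 2.36e-07 to 0.205). Il6, higher, read 155 ± 213 against 1.44 ± 0.281 (adjusted p = 0.0256), a call that ended without any 1 of the arrays labelled Trib1 null (adjusted p = 0.0863 to 0.123).

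Cell cycle genes shifted up slightly: 16 of 41 rose and 5 fell (16 and 7 adjusted over the list alone), with adjusted p = 0.00885, adjusted p = 0.540 with an estimated correlation, and a lower direction under equal medians (adjusted p = 0.960, range over alternatives 2.57e-05 to 0.960). The replication genes Mcm2, Gins1 and Cdc45 rose 1.78-fold, 1.65-fold and 1.62-fold. E2f1, a transcription factor of S phase entry, read 299.5 ± 231 against 501 ± 57.7 (adjusted p = 0.0402), lost without Trib1 hi 1 (0.129), Trib1 hi 2 (0.213) or Trib1 null 1 (0.0637, range over alternatives 0.00837 to 0.869). After quantile normalization the log2 difference of E2f1 went from -1.06 to -0.08 and its call ended (adjusted p = 0.521).

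**Figure D3:**
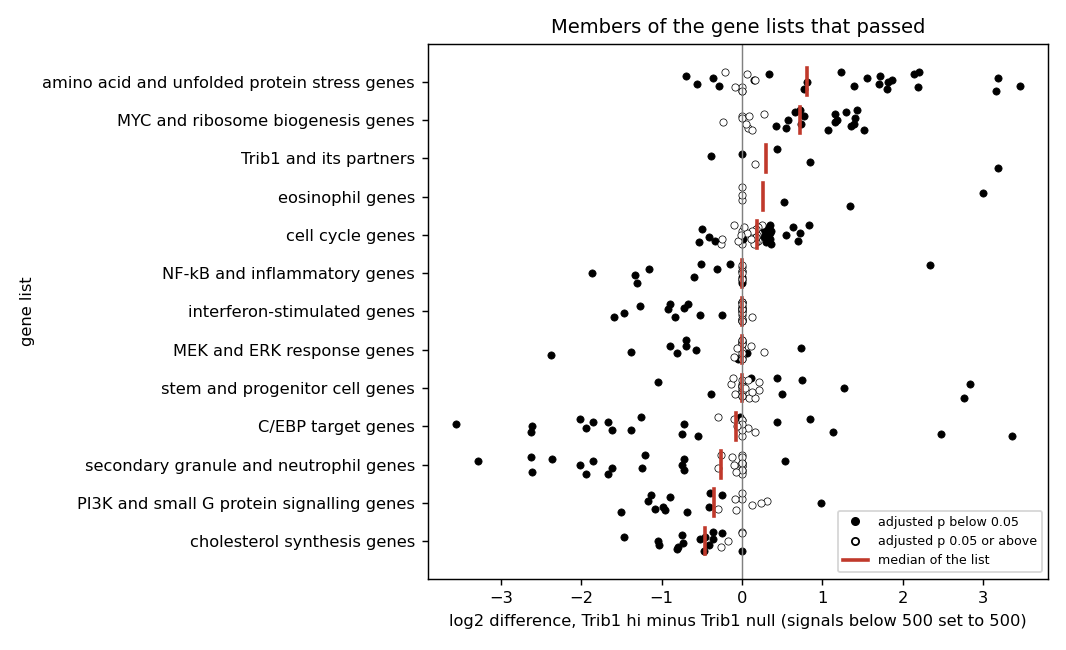
Log2 difference, Trib1 hi minus Trib1 null, with signals below 500 set to 500, for each tested member (points; filled, adjusted p below 0.05) of the 13 lists that passed; the red line is the list's median. Cell cycle members lie close to 0, and under equal medians that list's direction turned to lower (adjusted p = 0.960). Members of the amino acid and unfolded protein stress list reach both sides of 0.

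Other lists did not shift. IL-3 and STAT5 response genes rose in 4 of 17 cases and fell in 4 (5 and 4 adjusted over the list alone, adjusted p = 0.503; median log2 difference 0.21, mean -0.02): Socs2 rose 2.55-fold, whereas Socs3 fell at least 2.15-fold and the cyclin Ccnd3 2.02-fold. The IL-3 receptor subunit Il3ra read 269 ± 230.2 against 547 ± 17.4 (adjusted p = 0.00959), with overlapping groups, since Trib1 hi 3 read 577, and a call that ended with a floor of 500 (0.352, range over alternatives 0.000773 to 0.876). Hypoxia and glycolysis genes fell in 7 of 19 cases and rose in 1 (7 and 1 adjusted over the list alone, adjusted p = 0.0616). The glycolytic enzyme Aldoc fell 4.95-fold (826 ± 53.6 against 4083 ± 136), the angiogenic factor Vegfa 1.85-fold and the oxygen sensor Egln3 1.80-fold. Car9 read 193 ± 235 against 369.9 ± 33.9 (adjusted p = 0.0399), lost without Trib1 hi 1 or 2 or Trib1 null 1, 2 or 3 (0.0531 to 0.156). After quantile normalization the log2 difference of Car9 went from -2.26 to -0.16 and its call ended (adjusted p = 0.476). The hypoxia list passed downwards without Trib1 hi 1, 2 or 4 or Trib1 null 1, 3 or 4 (adjusted p = 0.0243 to 0.0438, range over alternatives 0.00145 to 0.632). Of 16 p53 targets, 8 fell and 3 rose (9 and 3 adjusted over the list alone, adjusted p = 0.0622, 0.0384 without Trib1 hi 1 and 0.0364 without Trib1 hi 2, range over alternatives 4.86e-05 to 0.337). The death receptor Fas fell at least 1.24-fold and the nuclease Aen rose at least 1.88-fold. Phlda3 read 47.8 ± 80.8 against 352 ± 86.9 and Zmat3 83.3 ± 142 against 303 ± 67.5; the first call (adjusted p = 0.0122) ended without Trib1 null 1, 3 or 4 (0.0637 to 0.0802) and the second (0.0303) without each array except Trib1 hi 3 (0.0552 to 0.117).

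Apoptosis regulators fell in 7 of 20 cases and rose in 1 (7 and 1 adjusted over the list alone, adjusted p = 0.364), with Apaf1 1.90-fold, the BCL2 family members Pmaip1 1.46-fold and Bak1 at least 1.42-fold lower, and Bmf at 34.3 ± 56.9 against 253 ± 84.5 (adjusted p = 0.0430, 0.0836 to 0.173 without each array except Trib1 hi 3). Adhesion and homing genes fell in 8 of 22 cases and rose in 3 (8 and 4 adjusted over the list alone, adjusted p = 0.401): Cd44, the hyaluronan receptor, rose 5.08-fold (4369 ± 649 against 857 ± 98.5), whereas Vcam1 fell at least 2.23-fold and the integrin Itgb3 at least 2.69-fold. Of 14 dendritic cell and MHC class II genes, 3 fell and 0 rose (3 and 0 adjusted over the list alone, adjusted p = 0.409; median log2 difference 0.34, mean -0.25): the class II loading genes H2-DMa (at least 2.56-fold), H2-DMb1 (at least 2.67-fold) and H2-DMb2 (2.18-fold), neighbours on chromosome 17. The call of H2-DMb2 was lost where probe sets shared between transcripts were left out (adjusted p = 0.973, range over alternatives 2.56e-17 to 0.973).

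Of 15 lymphoid genes, 1 rose and 1 fell (1 and 1 adjusted over the list alone, adjusted p = 0.241, 0.00789 without Trib1 null 3 and 0.00655 without Trib1 null 4, both upwards, range over alternatives 0.00655 to 0.777): Thy1, a surface glycoprotein, rose at least 16.4-fold (8337 ± 1477 against 267 ± 56.9) and Notch1 fell 2.22-fold. Of 9 fibroblast and endothelial genes, 1 rose and 2 fell (1 and 2 adjusted over the list alone, adjusted p = 0.586, 0.0257 without Trib1 null 3 and 0.0237 without Trib1 null 4, upwards, range over alternatives 0.0237 to 0.998), Thy1 again, smooth muscle actin Acta2 (at least 4.62-fold lower) and Pecam1 (1.39-fold lower). Of 18 erythroid and megakaryocyte genes, 1 rose and 1 fell (1 and 1 adjusted over the list alone, adjusted p = 0.688), Nfe2 (1.32-fold higher, with overlapping groups and adjusted p = 0.132 without a variance trend, range over alternatives 4.13e-08 to 0.184) and the carbonic anhydrase Car2 (1.91-fold lower). Hbb-b2, a beta-globin gene, was not on the list or among the named genes checked below, and was chosen after its values were seen. Its probe set, shared between transcripts, rose at least 12.6-fold (6330 ± 899 against 371 ± 65.7, adjusted p = 1.70e-22). None (0) of 8 widely expressed control genes passed (0 adjusted over the list alone, adjusted p = 0.305, 0.00353 upwards without Trib1 hi 3, range over alternatives 0.00353 to 0.777), with Pgk1 at 19833 ± 3299.9 against 16618 ± 1844 and Ywhaz at 13546 ± 2304 against 11328 ± 844. By limma, 0 of the 8 had an unadjusted p below 0.05; after quantile normalization 4 were higher and 1 lower at the adjusted threshold, and without Trib1 hi 3 and Trib1 null 1 together 6 were higher and 0 lower.

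Among named genes past the threshold, the groups overlapped for Nfe2, Il3ra, E2f1, Mvk, Car9 and Zmat3. Some calls of named genes ended when 1 choice of processing was changed. With the mean of all probe sets of a gene these were Acta2, Aen, Bak1, Bmf, Car9, Ccnd3, Cebpb, Cmpk2, Dhx58, E2f1, H2-DMa, H2-DMb2, Hsd17b7, Il3ra, Itgb3, Msi2, Mvk, Nfe2, Nfkbiz, Pdia4, Pik3cd, Pknox1, Rasgrp2, Rsad2, Snhg5, Socs2, Spry2 and Trib1 (adjusted p = 0.0521 to 0.860). Without a shared variance they were Adgre1, Bak1, Bmf, Car9, Ccl4, Cebpa, Cebpb, Clec7a, Cmpk2, Dhcr7, Dhx58, Dnajb9, Dusp2, E2f1, Ets1, Etv5, Fas, Gbp2, Gpnmb, H2-DMa, Hlx, Hoxa9, Hsd17b7, Id2, Il3ra, Il6, Isg20, Itgb3, Kit, Lrg1, Mpeg1, Mvk, Nfe2, Nfkbie, Nfkbiz, Pbx2, Pdia4, Phlda3, Pik3cb, Rap1gap2, Rasgrp2, Rsad2, Socs3, Spry1, Spry2, Tm7sf2, Trib1, Vav1, Vcam1 and Zmat3 (adjusted p = 0.0515 to 0.398). Without a variance trend they were Car9, Ccl4, Cebpb, Dnajb9, E2f1, Hsd17b7, Il3ra, Mvk, Nfe2, Pdia4 and Zmat3 (adjusted p = 0.0605 to 0.253).

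Of the sex-linked genes, 2 were tested and 1 fell (1 adjusted over the list alone): Xist lay at 102 or less on every array labelled Trib1 hi. The Y-linked genes Eif2s3y, Kdm5d and Uty lay at 43.8 or less on every array of both groups, in the range where arrays differ.

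Genes of chromosome 17 were lower together in the arrays labelled Trib1 hi. Over genes with a mean signal over 1000, the 237 on chromosome 17 had a median log2 difference of -0.49 against 0.02 for all such genes (permutation p = 1e-04, the smallest the draws can give; Benjamini-Hochberg p = 0.001 over 20 chromosomes), and 84.8% of them were lower. Of its 633 tested genes, 284 were called lower and 18 higher, against 2121 and 1344 of 11626 elsewhere. Relative to the other genes, the chromosome's median was -0.30, -0.30, -0.18 and -0.27 on the arrays labelled Trib1 hi and 0.27 on each array labelled Trib1 null. Chromosome 8 had a median of -0.18 (permutation p = 1e-04; Benjamini-Hochberg p = 0.001), carried by its middle part in gene order, where the median was -0.51 over 72 genes. Of the named genes, Lrg1, Pbx2, Pknox1, Nfkbie, Ccnd3, Vegfa, Bak1, Vav1 and the H2-DM genes, all lower, lie on chromosome 17, as does Adgre1, which was higher. Gene order and chromosomes are those of GRCm38.p6.

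**Figure D4:**
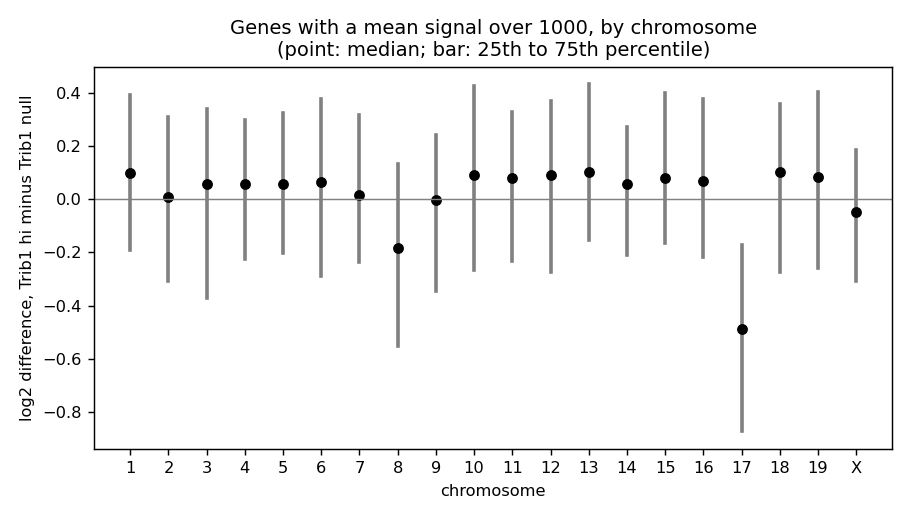
Median (point) and 25th to 75th percentile (bar) of the log2 difference, Trib1 hi minus Trib1 null, over genes with a mean signal over 1000, by chromosome. Chromosome 17 lies at -0.49 and chromosome 8 at -0.18, and the medians of the others lie between -0.05 and 0.10.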

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

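The tests of the low-intensity range, of lower expression at every brightness and of exchanged arrays were chosen after the results they bear on were seen; those over other splits of the arrays were not.

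In each group, every named gene was checked for an array standing apart from the other 3, by the gap to the nearest array divided by the range of the group, against Dixon's critical value, which chance passes in about 1 in 20 groups. Of 139 genes, 45 passed it in the group labelled Trib1 hi, 45 of them because of Trib1 hi 3, and 10 in the group labelled Trib1 null, 10 of them because of Trib1 null 1. The ratios for Trib1 hi 3 were Rgs5 0.938, Csn2 0.999, Xist 0.984, Alcam 0.958, Chil3 0.96, Erdr1 0.994, Lrg1 0.989, Ets1 0.992, Cd177 0.983, Trib1 0.99, Hoxa9 0.989, Meis1 0.972, Cebpa 0.889, Cybb 0.979, Mpeg1 0.994, Clec7a 0.97, Adgre1 0.915, Nfe2 0.895, Thy1 0.865, Id2 0.992, Hlx 0.997, Spry2 0.987, Spry1 0.977, Dusp2 0.853, Rsad2 0.995, Dhx58 0.993, Cmpk2 0.951, Gbp2 0.986, Nfkbie 0.99, Nfkbiz 0.997, Atf5 0.867, Fas 0.984, Phlda3 0.993, Zmat3 0.998, Bmf 0.994, Vcam1 0.987, Pik3cb 0.832, Pgk1 0.899, Isg20 0.869, Map2k1 0.927, Sdf2l1 0.88, Dnajb9 0.872, Snhg5 0.861, H1f2 0.961 and Aqp9 0.964. Those for Trib1 null 1 were Ptgds 0.951, Nkg7 0.933, Cd34 0.988, Cd177 0.856, Erg 0.831, Dmkn 0.97, Elane 0.972, Alox5 0.98, Etv5 0.978 and Bak1 0.961. The same arrays stood apart in the array median (0.987 for Trib1 hi 3 and 0.941 for Trib1 null 1), and Trib1 hi 3 in the GC25 background control (0.990).

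More genes were lower than higher in the arrays labelled Trib1 hi. On the deposited scale, calls were not mostly lower at every brightness: 56.2% were higher among genes with a mean signal over 2000. Bright probe sets largely set the trimmed mean to which each array is scaled, which holds bright genes near balance. That share therefore cannot decide whether expression before scaling was lower throughout. An uneven low-intensity range of the deposited signals remains a candidate explanation: the bacterial control bioB, added at a fixed amount, had a mean log2 difference of -2.48 over its 3 probe sets, though the groups overlapped, with Trib1 hi 3 highest of the 8 arrays for the 3' probe set (414). The dap controls, with group means from 610 to 2963, were lower without overlap (-0.50, -0.84 and -0.54), so a difference between the groups reached signals above 500. The bioC controls, with group means from 709 to 1322, were lower by -0.34 and -0.33 with overlapping groups, and bioD and cre, at 7376 and above, differed by 0.06 or less. Whether the dap difference has the same source as the uneven low range was not tested. What made the low range uneven, whether MAS5, the scan or the labelling, was not tested, and no biological explanation was tested for the split.

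A split and its mirror are the same split, so each of the 35 splits of the 8 arrays into 4 and 4 was counted by the larger of its values for both directions. Only the real split gave 2405 or more genes in a direction, against 1429 in the highest other split. Its share, 1 of 35, is the smallest this test can give, and the arrays of a group may be technical copies. Chance is therefore not excluded for the genes called lower. As many genes in a direction as the 1362 called higher came from 2 splits (highest other 1429), as many as the 275 at 2-fold higher from 2 (1397) and as many as the 1202 at 2-fold lower from 2 (1397), so chance cannot be excluded for these counts by this test. Compared with the smaller direction of each split instead, a comparison made after seeing these values, 1362 and 275 came from the real split alone (highest other 262 and 0), so for genes called higher the answer depends on the direction compared. A single other split supplied all those values: Trib1 hi 1, 2 and 4 with Trib1 null 2 against the rest, where 1429 genes were lower, 1397 of them by 2-fold, and 262 higher, 0 by 2-fold. It sets Trib1 hi 3 and Trib1 null 1 on the same side, as do other splits that gave 0 genes. As many lists in a direction as the 6 up came from 30 splits (highest other 11), and as many as the 7 down from 24 (11), so chance cannot be excluded for the number of lists; by the smaller direction, 6 came from the real split alone (highest other 4).

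Trib1 and Hoxa9 both read lower in the arrays labelled Trib1 hi. After quantile normalization with signals below 500 set to 500, the Hoxa9 difference was still -0.92 on the log2 scale (SE 0.058, adjusted p = 2.34e-07). It is a bound, since all arrays labelled Trib1 hi lie below 500. It argues against the uneven low range as the whole cause for Hoxa9 only as far as these steps remove that unevenness. As deposited, a dap control of like brightness in the group labelled Trib1 null (610 against 1073) differed by -0.84. Hoxa9 differed by -4.89 as deposited and by -2.49 after quantile normalization alone. The dap difference after these steps was not computed. Quantile normalization took bioB from -2.48 to -0.15 and the GC25 background control to -0.23. It left Trib1 at -2.24 (SE 0.19, adjusted p = 1.35e-07). This cannot decide the cause for Trib1, since on the arrays labelled Trib1 null Trib1 (206 to 304) lay at the level of that control (149 to 335). The other Trib1 probe set read 9.05 ± 12.6 against 6.98 ± 6.54. An exchange of single arrays between the groups is argued against by the lowest Spearman correlation within a group, which exceeded the highest between groups by 0.00558. Most probe sets in these correlations lay below 500, in the range where arrays differ. An exchange of both whole groups, an introduced sequence without the part the probes read, and a real difference in Hoxa9 and Trib1 RNA stay open and untested; Pik3cd and Spns2, singled out by the study, were 1.99-fold and at least 1.67-fold higher in the arrays labelled Trib1 hi, which does not bear on an exchange made before the study chose them.

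Probe sets without a single gene name were outside the comparisons. Of 16139, 2294 exceeded 500 on at least 1 array; with signals below 500 set to 500, 98 were at least 2-fold higher and 81 at least 2-fold lower in the arrays labelled Trib1 hi.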

How the results depend on the processing

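The alternatives chosen after seeing the data were the floors of 500 and 1000, quantile normalization with a floor of 500, leaving out both raised arrays, and leaving out chromosomes 8, 17 and X; the others were planned. Over all alternatives the named genes gave 3531 values: 3279 stayed, 200 lost the call, 19 gained 1 and 33 turned. Of 679 list values, 581 stayed, 51 lost and 46 gained a call and 1 turned. A value that stayed kept its side of the threshold, and its direction where it was past the threshold. A value past it in neither test counts as staying whatever its direction, as for primary granule genes after quantile normalization. The causes were not tested. Low signal over background limits every value under about 500.

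Counts are given as higher, lower, at least 2-fold higher and at least 2-fold lower, against 1362, 2405, 275 and 1202. Quantile normalization gave 3336 higher and 882 at 2-fold higher. Equal medians gave 5440, 250, 5440 and 250, with 3 lists down. The mean of all probe sets of a gene gave 725 and 1317, with 718 at 2-fold lower. Without a variance trend 1272 were lower and 603 at 2-fold lower; without a shared variance 802 were higher, 850 lower and 238 at 2-fold lower. A floor of 500 gave 336 at 2-fold lower, a floor of 1000 gave 1420 lower, 132 and 162 at 2-fold and 3 lists up, and quantile normalization with a floor of 500 gave 2213 higher, 300 at 2-fold lower and 3 lists up. Without both raised arrays 2682 were higher, 3899 lower and 2359 at 2-fold lower, with 4 lists down. With an estimated correlation 1 list was up and 2 down (against 6 and 7), and fry put 12 down. Leaving out 1 array gave 1153 to 2092 higher, 1967 to 3762 lower, 254 to 327 and 890 to 2323 at 2-fold, 5 to 10 lists up and 4 to 9 down; the highest gene counts and the 4 lists down came without Trib1 hi 3, and 10 lists up without Trib1 null 3 or 4.

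The Trib1 difference of -3.72 lost its call with the 50th percentile as pseudocount (-3.50), with no filter (-3.72), with the mean of its probe sets (-1.86), without a shared variance (-3.72), and without chromosomes 8, 17 and X (-3.72); leaving out 1 array gave -4.65 to -3.36. It kept its call after quantile normalization (-2.24, adjusted p = 1.35e-07), under equal medians (-1.73, adjusted p = 0.0298), with a robust variance prior (adjusted p = 0.00722) and without both raised arrays (-4.52, adjusted p = 0.0001). Floors gave no value for Trib1, and Xist and other genes of left-out chromosomes had none there.

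Deviations of same-numbered arrays correlated at -0.54, 0.51, -0.32 and 0.32, and at -0.03 to 0.02 after quantile normalization, so the numbers are not taken to pair arrays. The replicate block gave 1285 higher, 2344 lower, 270 and 1182 at 2-fold, 10 lists up and 9 down, and -3.72 for Trib1 (adjusted p = 0.10).

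Under equal medians, which moved the median log2 difference of tested genes from 0.04 to 2.02, 31 named genes turned to higher, none past the threshold (smallest adjusted p = 0.151): Pbx2 0.13, Pknox1 1.41, Dach1 0.40, Ccl3 0.65, Car2 1.05, Notch1 0.84, H2-DMb1 0.37, H2-DMb2 0.86, Pecam1 1.51, Il3ra 0.51, Ccnd3 0.97, E2f1 0.92, Dhcr7 0.45, Hsd17b7 0.55, Vegfa 1.09, Egln3 1.14, Bak1 0.69, Apaf1 1.06, Pmaip1 1.44, Itgb3 0.11, Vav1 0.68, Pik3cb 0.73, S100a9 0.039, Dusp6 0.60, Nsdhl 0.94, Lmo2 0.94, Map2k1 1.59, Creld2 1.29, Sdf2l1 1.42, Dnajb9 1.62 and Pdia4 1.69. The cell cycle list turned to lower there (adjusted p = 0.960). With a floor of 500, E2f1 0.018 and Car9 0.0069 turned to higher.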

Other observations

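The bright genes outside the lists and the tests of neighbouring genes and of chromosome copies were chosen after their values were seen; the test over the brightest chromosome 17 genes was not.

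Several bright genes outside the lists differed strongly by the same model. In the arrays labelled Trib1 hi, the host transcripts of small nucleolar RNAs Zfas1 and Snhg5 were 8.27-fold (15792 ± 2799 against 1895 ± 243) and 4.02-fold (8103 ± 1185 against 1996 ± 33.9) higher, alongside the ribosome assembly genes. The histone genes H2bc4 and H1f2 were 5.60-fold and at least 5.75-fold higher. Mreg and Rab38, known from transport of pigment granules, were at least 12.7-fold and 5.54-fold higher, and Aqp9, a channel for water and glycerol, at least 8.34-fold. Lower were Slfn4, a myeloid Schlafen gene (8.15-fold; 1262 ± 78.9 against 10301 ± 838), Cd24a, a surface sialoglycoprotein (6.57-fold; 2577 ± 269 against 16922 ± 1597), the homeodomain protein Hopx (6.16-fold), Crip1 (5.62-fold) and the metalloproteinase inhibitor Timp2 (at least 13.5-fold). The largest adjusted p among these 12 was 2.88e-16; the Snhg5 call ended with the mean of its probe sets (adjusted p = 0.222, range over alternatives 1.59e-74 to 0.222).

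Genes of chromosome 17 were lower across its length. The uneven low-intensity range is argued against as the cause: over the 58 genes with a mean signal over 5000 the chromosome's median lay -0.40 from that of the other chromosomes, where 10000 random draws gave -0.19 to 0.16 (permutation p = 1e-04, the smallest they can give). A few strongly changed neighbours are also argued against, since 84.8% of the 237 genes with a mean signal over 1000 were lower. At least 78.5% were lower in each of 3 parts of the chromosome in gene order, which the share over all 237 largely fixed. A hypothesis that fits is a different number of copies of chromosome 17 in the cells of both groups: the highest median of the 3 parts was -0.39, and a whole-chromosome difference would need every part below 0. These medians come from the same genes and are no separate evidence. Copy number was not measured, and gains or losses of this kind may arise in culture without a bearing on Trib1.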
